A study of Rattus norvegicus with 6 samples.

How the data were processed

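RNA was sequenced from 6 libraries of GH3 cells, 3 of untreated controls and 3 of cells given 100 nM thyrotropin-releasing hormone (TRH). Per the labels' protocols, libraries were made from total RNA after agarose gel and Qubit checks and sequenced on an Illumina XTen instrument. The submitters' processing notes name HISAT2 and bedtools, with no version, role or order. The genome build, annotation release, strand setting, counting rule for overlapping genes or near-identical copies, and duration of the TRH treatment are not given in the sources used here.

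The authors deposited raw read counts per Ensembl gene for 18413 genes, all of which had a count in at least 1 library. A second deposited table repeats these counts, equal in 100% of cells, and adds a gene length in bases, FPKM and TPM. The authors' FPKM equal the count divided by the table's gene length in kilobases and the library's total count (per 1e6 counts) and were recomputed here to rounding error. The authors' TPM equal the FPKM of each library rescaled so that every library has the same total, also recomputed to rounding error. How the deposited gene length was taken from the annotation is not given in the sources used here. Of these lengths, 44.0% were multiples of 3, so they are not coding lengths alone. Because FPKM and TPM divide by 1 fixed length per gene, neither removes a trend with gene length that differs between libraries.

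Both tables name genes by Ensembl identifier only. The reference table used here (RefSeq, assembly GRCr8) holds an Ensembl identifier in 0 of its 47357 rows, so 0 identifiers were matched to a symbol. No gene was named from its identifier. The prolactin gene and the other genes chosen by symbol before the data were examined, and the 20 gene lists fixed at the same time (pituitary hormone cell markers, markers of other cell types, immediate early genes, calcium and PI3K signalling, secretory granules, proliferation, stress and metabolic pathways), are not analysed here. The rule for reporting genes was to give the chosen symbols, the 10 genes with the largest rise and the 10 with the largest fall past the threshold, and up to 4 members of each list. No gene came under the second part, since none passed. The 4 identifiers printed instead, 2 in each direction, were chosen after their values were seen: those with the smallest p among genes whose control and TRH libraries did not overlap and whose mean log2 CPM was at least 1.

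The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM scaling, the filterByExpr filter, a two-group design without a replicate block, and Benjamini-Hochberg adjustment over the 14050 genes kept, at a threshold of 0.05. Fold changes are TRH over control. Standard errors were taken from the fitted coefficient and its F value, and 95% intervals from the t distribution with the fit's residual and prior degrees of freedom. CPM values were computed from the counts with TMM scaling. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No 2 libraries agreed within sampling noise: chi-square per degree of freedom ran from 13.7 to 110.0 over the 6 pairs within a group, on genes with at least 20 counts per pair.

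Replicate numbers 1 to 3 occur in both groups. Nothing in the labels ties equal numbers to a shared day or culture, so the numbers were not treated as pairs, a choice made before the data were examined. The deviations of equal-numbered libraries from their group means did not correlate in every pair. With 3 libraries per group this cannot rule out a pairing.

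Alternatives set before the data were examined were DESeq2 size factors within edgeR, DESeq2's Wald test (DESeq2 1.42.0), limma voom (limma 3.58.1), no filter, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, limma on log2(TPM + 1) and on log2(TPM + 0.1) for the same genes, limma on log2(TPM + 1) with a TPM filter and with no filter, glmTreat against a fold of 1.2, a log2 fold threshold of 1, and, in edgeR, leaving out each library in turn. Alternatives added after seeing the data were offsets for gene length (a loess of each library's log2 CPM deviation on log2 length, span 0.5), leaving out control replicate 1 and TRH replicate 3 together, and, for DESeq2, leaving out each library in turn, a block, thinned counts and the filterByExpr genes. Genes were also divided by length and by mean abundance into 5 groups of equal size, called length group 1 (shortest) to 5 (longest) and abundance group 1 (lowest) to 5 (highest), a division likewise made after seeing the data.

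The fits were tested on simulated data. Counts for the 14050 genes of this comparison were drawn from the real means and library sizes, with 200 genes changed. The changed genes were taken from those with a mean log2 CPM above 1, so the rates below do not cover less abundant genes. Dispersions were drawn around edgeR's fitted trend, with a spread set by the fit's prior degrees of freedom (4.13). Values drawn in this way lie above the trend on average. That prior describes edgeR's quasi-likelihood dispersions, so the simulated spread may differ from the real one and the setting may favour edgeR. At a simulated 1.5-fold change edgeR called 6% of 50 changed genes, at 2-fold 48%, at 3-fold 72% and at 4-fold 92%, with 10 calls among unchanged genes. DESeq2 called 24%, 80%, 94% and 100% at the same folds, with 90 calls among unchanged genes. Depth ran from 43504159 to 52134239 counts per library, so 1 CPM stands for 43.5 to 52.1 counts. No column of another series was present in the tables.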

Results

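GH3 is a rat pituitary tumour cell line that makes growth hormone and prolactin, and TRH is a hypothalamic peptide that acts on pituitary cells through a G protein-coupled receptor. The transcriptome of GH3 cells was compared between 3 control libraries and 3 libraries of cells treated with 100 nM TRH, to find which messenger RNAs differ after the hormone. The control libraries held 45069808 ± 1434303 counts (SD, n = 3) and the TRH libraries 47646156 ± 3904844 counts (SD, n = 3). A count was present for 16266 ± 72.1 genes per control library (SD, n = 3) and for 16215 ± 129 genes per TRH library (SD, n = 3). The deposited tables name genes by Ensembl identifier alone, so genes are given by identifier and length, and the prolactin transcript is not analysed here.

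No gene's messenger RNA level in GH3 cells differed between control and TRH libraries past the threshold of the main test. Of 14050 genes tested, 0 passed the threshold in edgeR's quasi-likelihood test (smallest Benjamini-Hochberg adjusted p = 0.395), 1263 had an unadjusted p under 0.05, and DESeq2's Wald test, run as an alternative, called 106. The median absolute log2 fold change was 0.16, and 114 genes had a fitted log2 fold change of 1 or more in either direction. Limma voom called 0 genes, with 1257 at an unadjusted p under 0.05. The 1263 genes stand against 702.5 that a uniform distribution of p-values would give. Of them, 287 were higher and 976 lower with TRH, and with offsets for gene length the split was 726 higher and 795 lower of 1521.

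Among genes with higher values in TRH libraries, the smallest p belonged to ENSRNOG00000023896 (gene length 2754 bases). Its level was 10.3 ± 1.15 CPM in controls and 17.8 ± 0.793 CPM with TRH (SD, n = 3 each). The edgeR log2 fold change was 0.79 (SE 0.13, 95% interval 0.49 to 1.09, edgeR adjusted p = 0.395), and DESeq2's adjusted p was 0.000463. The next was ENSRNOG00000012988 (2866 bases), a less abundant transcript at 2.58 ± 0.197 CPM in controls and 4.96 ± 0.447 CPM with TRH (SD, n = 3 each). Its edgeR log2 fold change was 0.94 (SE 0.17, 95% interval 0.54 to 1.34, edgeR adjusted p = 0.395) and DESeq2's adjusted p was 0.00524. With each library left out in turn, DESeq2's adjusted p for ENSRNOG00000012988 was under the threshold in 3 of 6 fits and reached 0.167. In 1 fit DESeq2 gave this gene no adjusted p. The other 3 genes printed here stayed under the threshold in 6 of 6 fits, the highest value being 0.0472 for ENSRNOG00000023896. All printed genes were chosen for a small p and groups without overlap in these same libraries. Each fit reuses most of those libraries, so the choice itself favoured staying under the threshold, and these fits are no independent test.

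Among genes with lower values in TRH libraries, ENSRNOG00000060356 (4786 bases) had the smallest p of all genes tested. Its level was 15.5 ± 0.625 CPM in controls and 8.68 ± 0.298 CPM with TRH (SD, n = 3 each). Its edgeR log2 fold change was -0.83 (SE 0.12, 95% interval -1.10 to -0.57, edgeR adjusted p = 0.395), and DESeq2's adjusted p was 5.7e-05. The next, ENSRNOG00000053047 (5589 bases), was more abundant, at 205 ± 11.8 CPM in controls and 123 ± 14.8 CPM with TRH (SD, n = 3 each). Its edgeR log2 fold change was -0.73 (SE 0.11, 95% interval -0.98 to -0.48, edgeR adjusted p = 0.395) and DESeq2's adjusted p was 0.00023. For these 4 genes, the 3 control values and the 3 TRH values did not overlap, which was a condition of their choice. Chance gives such separation in 10% of genes with 3 libraries against 3, on average over the possible splits. Of the 14050 genes tested, 2385 showed it, 956 higher and 1429 lower with TRH. Genes are not independent, so the share in a single split can differ from 10% without any effect of TRH. It was not computed for other splits. Over 19 alternatives per gene, the adjusted p of these 4 genes was at least 0.307 in every one but DESeq2's test and reached 1.00.

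**Figure D1:**
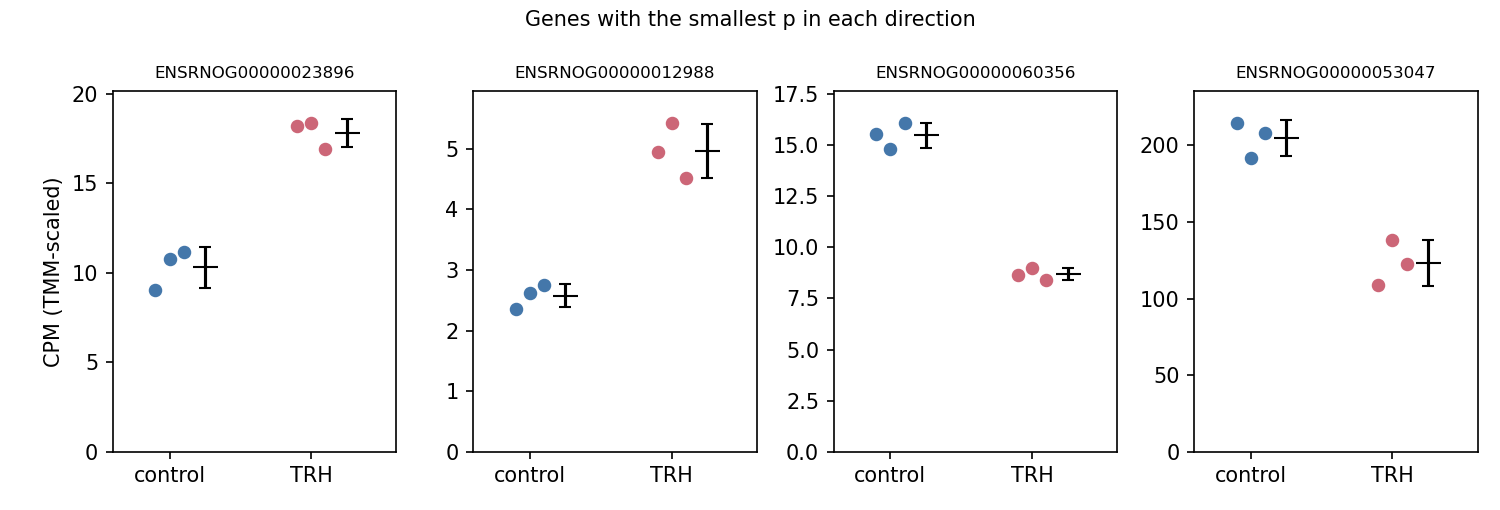
Each panel plots 1 gene's level in CPM (TMM-scaled, axis from 0) for the 3 control and 3 TRH libraries (points), with the mean and SD (bar). ENSRNOG00000023896 lies near 10.3 CPM in controls and 17.8 CPM with TRH, and ENSRNOG00000060356 near 15.5 CPM in controls and 8.68 CPM with TRH.

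The 106 genes called by DESeq2 were mostly lower with TRH, 93 against 13 higher. Their log2 fold changes ran from -0.9997 to -0.42 among the lower genes (median -0.65) and from 0.35 to 0.96 among the higher genes (median 0.52), and 0 of them reached an absolute log2 fold change of 1. All 106 had an edgeR p under 0.05. The lower genes had a median length of 4605 bases, the higher genes 2754 bases and all genes tested 2198.5 bases. Of the 106 genes, 62 lay in length group 5 (the longest of 5 groups of equal size, 3866 bases or more) and 1 in length group 1 (the shortest). The number called varied with the libraries used: DESeq2 called 25 genes without control replicate 1, 50 without control replicate 3, 10 without TRH replicate 1, 20 without TRH replicate 2, 43 without TRH replicate 3 and 169 without control replicate 2. Without both control replicate 1 and TRH replicate 3, the libraries that stood farthest apart, it called 42. With all libraries and the replicate number as a block it called 27, of which 19 were among the 106. In all 106 genes the control and TRH values did not overlap, so leaving out libraries could hardly turn the sign of a fold change, and none turned.

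Genes grouped by length differed in the direction of their fitted changes. In length group 1 (49 to 1176 bases), 62 genes were higher and 57 lower with TRH at an unadjusted p under 0.05, and the median log2 fold change was 0.12. In length group 3 (1852 to 2614 bases), 68 were higher and 163 lower, with a median of 0.00. In length group 5 (3866 to 29464 bases), 27 were higher and 406 lower, with a median of -0.11. edgeR called 0 genes in each of these groups. By abundance, the median log2 fold change was -0.05 in abundance group 2 of 5 (3.16 to 13.5 CPM), with 54 genes higher and 290 lower at an unadjusted p under 0.05. In abundance group 5 (81.3 CPM and above) it was 0.05, with 92 higher and 120 lower.

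The length groups also differed between libraries of the same treatment. The median deviation of length group 5 minus that of group 1, on the log2 scale and relative to each gene's mean over the 6 libraries, was 0.37 in control replicate 1 and -0.44 in TRH replicate 3. The remaining libraries gave differences of -0.17 in control replicate 2, 0.15 in control replicate 3, 0.06 in TRH replicate 1 and 0.02 in TRH replicate 2. The group values, 0.12 ± 0.27 in controls and -0.12 ± 0.28 with TRH (SD, n = 3 each), differed by less than their spread (two-sided exact permutation test, p = 0.4, where 0.1 is the smallest p that 3 against 3 allows).

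**Figure D2:**
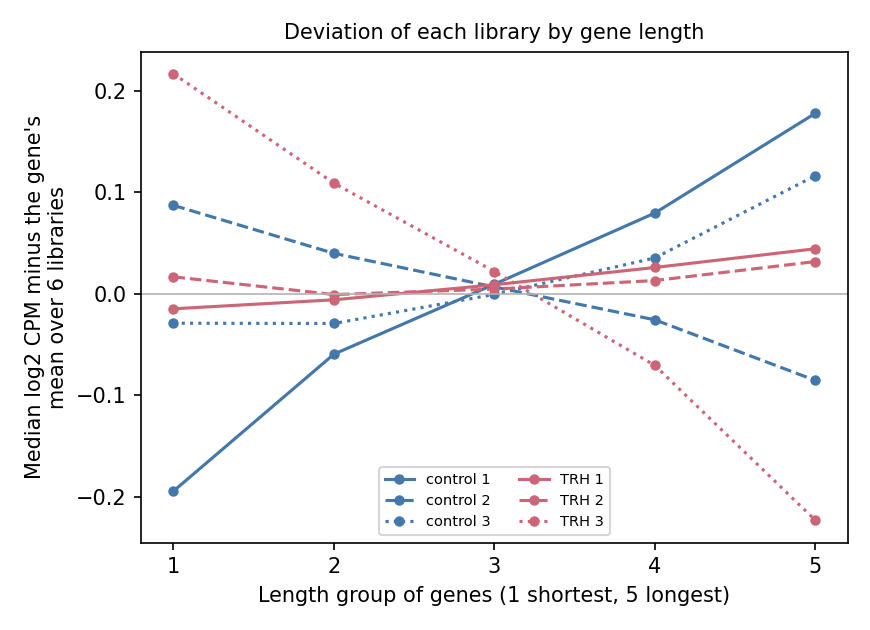
The horizontal axis gives 5 equal groups of the 14050 genes by length, from 1 (shortest) to 5 (longest), and the vertical axis the median deviation of log2 CPM from the gene's mean over the 6 libraries. Lines stand for libraries, and control replicate 1 (from -0.19 to 0.18) and TRH replicate 3 (from 0.22 to -0.22) run in opposite directions.

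The most abundant transcripts were unevenly distributed over the controls. The most abundant gene of each library took 2.15% of counts in control replicate 1, and between 1.09% and 1.41% in the other libraries. Of the 10 genes with the highest mean CPM, 3 were highest in control replicate 1, at 1.82, 2.01 and 1.40 times the mean of the other libraries. For the rest of the 10, control replicate 1 lay at 0.74 to 1.02 times that mean. TRH replicate 3 was highest for the genes ranked 5, 7 and 10. The 10 most abundant genes took 6.55 ± 0.820% of counts in controls and 5.87 ± 0.258% with TRH (SD, n = 3 each).

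The first principal component of log2 CPM held 43.2% of the variance and set control replicate 1 (-43.2) against TRH replicate 3 (39.5), with the other 4 libraries between -8.72 and 12.9. The second component held 21.9% and did not separate the treatments, since control replicates 1 and 2 (-20.3 and -18.7) and TRH replicate 3 (-13.3) lay on one side. Across genes, which are not independent replicates, Pearson's r between libraries was 0.979 to 0.991 within a group and 0.968 to 0.990 between groups.

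**Figure D3:**
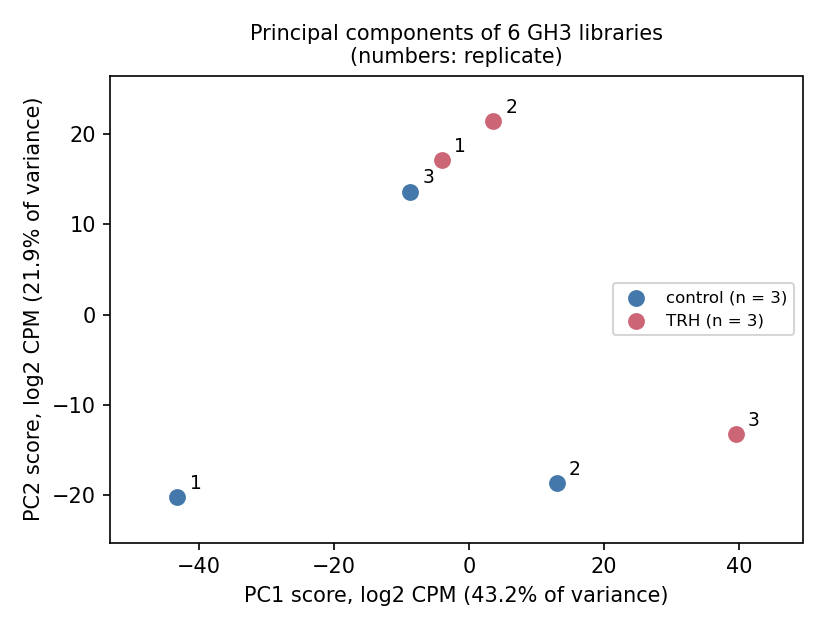
Each point is a library placed by its score on the first (43.2% of variance) and second (21.9%) principal components of log2 CPM, coloured by treatment and numbered by replicate. Control replicate 1 and TRH replicate 3 lie at opposite ends of the first component, and neither component separates the treatments.

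Taken gene by gene, the 95% interval of the fold change excluded a 2-fold change for most genes. These intervals are not adjusted for the number of genes tested. They rest on the spread between these samples, which may be technical, and cover only a treatment of unstated duration. The 95% interval of the fold change lay wholly within 2-fold in either direction for 11517 genes (82.0%) and within 1.5-fold for 7666 genes (54.6%). The share within 2-fold was 98.0% in abundance group 5 and 33.2% in abundance group 1 (the least abundant), where a change of that size was often not excluded. The spread between libraries of a group corresponded to a biological coefficient of variation of 17.1%.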

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

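The number of genes called, 0 in edgeR with 1263 at an unadjusted p under 0.05, was 0 again with DESeq2 size factors, limma voom, no filter, the stricter CPM filter, limma on log2(TPM + 1) under 3 filters, limma on log2(TPM + 0.1) for the edgeR genes, glmTreat, a log2 fold threshold of 1 and length offsets. DESeq2's Wald test called 106, and 126 on the genes of the edgeR filter without independent filtering, so neither its size factors (0 in edgeR) nor its filtering accounts for the difference from edgeR. Thinned counts gave 100 in DESeq2. In edgeR, leaving out single libraries gave 0 to 1 genes, the 1 without TRH replicate 3, and leaving out control replicate 1 and TRH replicate 3 together gave 1. The 1263 genes became 519 with glmTreat, whose stricter null lowers the count by construction, and 769 to 1786 with single libraries left out, the lowest without control replicate 1. DESeq2's 106 became 164 with length offsets, 42 without control replicate 1 and TRH replicate 3 together, and 10 to 169 with single libraries left out, the lowest without TRH replicate 1. For the 4 identifiers, chosen for libraries that did not overlap, the direction could hardly turn and did not in 76 alternative values, and 4 of these passed adjustment, each in DESeq2's test. Alternatives for prolactin and the gene lists were not run, because no identifier was matched to a symbol. The interval of the fold change lay within 2-fold for 33.2% of genes in the lowest abundance group and 98.0% in the highest.

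With the replicate number as a block (replicate block), edgeR called 0 genes, with 1232 at an unadjusted p under 0.05, and DESeq2 called 27. Deviations of equal-numbered libraries correlated at 0.29 for number 1, -0.26 for number 2 and -0.12 for number 3, and control replicates 2 and 3 each correlated best with a TRH library of another number.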

Other observations

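All tests in this part were added after the data had been seen. For length offsets, thinning, simulated draws and other splits of the DESeq2 count, what each outcome would mean was written before that test was run. For the share of genes lower with TRH and other splits of the edgeR counts it was written after.

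The fold change with TRH fell with gene length: the median log2 fold change of length group 5 (longest) minus that of group 1 (shortest) was -0.23 with all 6 libraries. It was -0.11 without control replicate 1, -0.36 without control replicate 2, -0.22 without control replicate 3, -0.32 without TRH replicate 1, -0.30 without TRH replicate 2 and -0.07 without TRH replicate 3. Without both control replicate 1 and TRH replicate 3 it was 0.051, which follows from their being the control with the highest and the TRH library with the lowest value of this measure, and so tests nothing. The untreated controls alone ranged from -0.17 to 0.37 in their deviation from the mean of the 6 libraries. The sources used here give no RNA integrity value per library.

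Whether the trend with length between libraries is the whole cause of the excess of genes lower with TRH was left open. Of the genes at an unadjusted p under 0.05, 77.3% were lower with TRH in all 6 libraries and 52.3% with length offsets. The offsets centre each library at each length and would also remove an effect of TRH that depends on length, so that share does not decide. Without control replicate 1 and TRH replicate 3 the share was 71.1%, which lies within the 67.6% to 87.0% given by leaving out single libraries. In that fit the median log2 fold change of length group 5 minus group 1 was 0.051. The excess of lower genes was thus present there without a fall of the medians with length. The shares under the offsets and in that fit differ, so the question stays open. The 106 genes called by DESeq2 changed less: 88 were called again with length offsets, under which 131 of 164 calls were lower. The median length of the lower calls was 3466 bases with offsets and 4605 bases without. The offsets take out the average trend at each length. In length group 5 the median log2 fold change was -0.11, while every lower call reached -0.42 or beyond. A shift of that size could hardly remove most calls, which were chosen for small p in these same libraries. The repeated calls are thus weak evidence against that trend as a cause. Its size alone falls short of the folds of the lower calls. Differences between genes of one length stay uncorrected, so a cause related to length is not excluded. With all libraries thinned to one depth 95 were called again, but library totals differed too little for that to test a difference in library size. A response to TRH, and a difference in culture or handling that followed the treatment, may each account for part of the remaining genes. Neither was tested. Calls made with no gene changed, and structure among the libraries unrelated to treatment, may account for part of them too.

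DESeq2 may make part of its calls with no gene changed, as it did at the simulated spread. In 20 simulated draws for this comparison with no gene changed among 14050, DESeq2 called a median of 33 genes (18 to 46), of which a median of 48.8% were lower, against 106 calls with 87.7% lower in the real libraries. edgeR called 0 to 1 genes in the same draws. The draws assume independent genes and no structure among libraries, so they leave open how much of the 106 a shared structure could add. Their dispersions were drawn from edgeR's fit, which may favour edgeR, so they do not rank edgeR against DESeq2.

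The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. DESeq2 called 106 genes in the real split and at most 83 in another, so 1 of 10 splits, the real one, reached that value. The split with 83 set control replicates 1 and 2 and TRH replicate 3 against the rest, as the second principal component does. At an unadjusted p under 0.05, edgeR gave 1263 genes in the real split and 1795 in the split of control replicates 1 and 3 and TRH replicate 1 against the rest, so 2 of 10 splits, the real one included, reached the real value. The same split gave 4 DESeq2 calls against 106. All 3 libraries on its first side had the longest genes above the shortest, as TRH replicate 2 on the other side had by 0.02. By adjusted p edgeR called 0 genes in the real split and at most 1 in another, and 10 of 10 splits reached the real value, as they must when it is 0.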
